A study of Mus musculus with 4 samples.

How the data were processed

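The series holds 4 samples, an RNA and an ATAC library for each of 2 host genotypes, WT and IEC-Ceacam1-/- in the labels, here called Ceacam1-deficient; groups were taken from the recipient genotype in the labels. Per the labels' protocols, the cells were sorted CD4+ T cells of donor type, and libraries were made with the 10x Genomics Multiome kit, which joins RNA and ATAC of a nucleus by barcode. Per the file headers, the matrices and peak lists were written by Cell Ranger ARC 2.0.0, and the genome build was mm10, per the submitters' processing notes and the peak file headers. The deposited matrices hold raw counts, UMI counts per gene and ATAC cut site counts per peak, not normalized, for 20000 barcodes per library. Per the file headers, peaks were called in each library on its own; the peak lists carry positions with no score, and the annotation tables give each peak's gene, distance to the transcription start site and class (promoter, distal or intergenic). Whether intronic reads were counted is not given in the sources used here.

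Barcodes were kept with at least 500 UMIs, 300 genes and 500 ATAC counts, at most 10% mitochondrial UMIs, and no doublet call. Of 20000 barcodes each, 15 WT and 643 Ceacam1-deficient barcodes had under 500 UMIs, 2832 and 7123 were over the mitochondrial limit, and 15331 and 11094 were kept, with 120284414 and 37383135 UMIs. Doublets were scored in each library by the share of simulated doublets (2 per cell) among a cell's neighbours in 30 principal components, and the top 10% of scores were left out (1907 and 1903). That fixed rate replaced an automatic threshold after its calls had been seen to differ strongly between the libraries. The strict filter asked for 1000 UMIs, 600 genes, 1000 ATAC counts and at most 5% mitochondrial UMIs. No barcode list of the authors' own cells or cell types was used.

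Raw counts were summed over the kept cells of each library and scaled to CPM of the library's total. A gene's ratio carries an exact conditional binomial 95% interval, levels an exact Poisson and shares an exact Clopper-Pearson binomial interval. All of these cover counting error only; with 1 library per genotype there is no spread between animals, and no p-value, standard error or count of changed genes was made. A gene with no UMI in a library was set to a floor of 3 counts there, and no fold of such a gene is reported. Ratios of lists are medians over members at 5 or more mean CPM; the interval comes from 10000 resamplings of the members, and the percentile from 10000 random lists of the same size matched on mean expression in 20 bins. Scaling did not shift the genes as a whole: the median ratio over 9885 genes was 0.02. Gene positions and lengths (genomic span) came from a RefSeq table of GRCm38.p6, the assembly behind mm10, matched on symbol; 9591 of 9885 genes at 5 CPM or more (97.0%) had a length.

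Before the data were examined, 20 gene lists, a panel of genes, 13 marker and check lists and the tests were fixed. The named genes were the 10 with the highest and the 10 with the lowest ratio at 20 or more mean CPM whose interval excluded a ratio of 5 to 4 and whose direction held under every scaling, leaving out Gm-number, Rik, ribosomal-protein, mitochondrial, sex-linked and antigen-receptor genes; the panel; and up to 4 members of each list with the largest ratios at 5 or more mean CPM. Some genes that this rule names are not reported here. For ATAC the rule named the 5 regions with the highest and the 5 with the lowest ratio at 20 or more CPM. Named after the data were seen were Cd4, Cd8a, Cd8b1 and Cd3e, the leading genes of clusters, Mcm2, Mcm6 and Pcna, the single genes of marker and sex-linked lists, and the choice of which lists and which differences between clusters to lead with. The lists were cytotoxic, Th1, Th2, Th17 and Th22, Treg, Tfh, naive and central memory T, coinhibitory receptors and exhaustion, activation and costimulation, homing and tissue residence, type I interferon response, cell cycle, glucocorticoid response, nuclear receptors and efflux, glycolysis, fatty acid and oxidative metabolism, survival and apoptosis, cytokine receptors, immediate early and stress, and T cell core; markers covered CD8 T, gamma delta and innate-like T, NK and ILC, B, plasma, macrophage and monocyte, dendritic, neutrophil and mast, erythroid and megakaryocyte, stromal, endothelial and epithelial and immature thymocyte-like cells, and sex-linked genes were listed too. A list of host class II genes (H2-Ea) matched no gene name here and gave no value.

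Cells were clustered together (Leiden, resolution 1, 15 neighbours, 30 principal components of 2000 variable genes ranked within each library) after the deeper library was thinned to the other's median UMIs. Genes seen in at least 20 cells were ranked by their ratio of variance to mean against genes of like mean. Mitochondrial, ribosomal-protein and sex-linked genes and the variable, diversity and joining segments of antigen receptors were left out. Constant-region genes such as Igkc, Ighg1 and Igha stayed eligible. Values were log-normalised, scaled and limited to 10 units either way. Clusters were named by hand, as "-like" a type, from the fixed markers among their 10 and 100 leading genes by fold (10 CPM added to both sides); others stayed unnamed. Cluster names, the Cd4-high and Cd8a-high groups and the clusters left out in some values, cells of 4000 to 8000 UMIs, the run without a mitochondrial limit, depth matched rank by rank and lists matched on length were settled after the data were seen. Ratios within a class were computed where each library had 200 cells or more, which leaves out Th17 and Th22-like cells (190 in the Ceacam1-deficient host). For shares of cells with a UMI, each cell was thinned to 1000 UMIs.

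ATAC counts were compared over regions made by merging overlapping peaks (1 bp or more) that held a peak of both libraries, scaled to their total. Even counts made up 82.2% and 83.9% of the entries, since both ends of a fragment are counted, so intervals were taken on fragments; this was decided after the data were seen. Promoters were the regions the deposited annotation calls promoter for a gene. Spearman's rho used genes at 5 or more mean CPM and 20 or more promoter CPM, with an interval from 1000 resamplings of genes.

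The calculations for genes, peaks and lists were tested on simulated data with known changes drawn from the real libraries' levels. For the comparison of hosts, of 6841 genes simulated, 67 of 67 changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 3-fold were found, and 0 of 6641 unchanged ones. Of 13533 peaks, 67 of 67, 67 of 67 and 66 of 66 changed 1.5-, 2- and 3-fold were found, and 0 of 13333 unchanged. Of lists of 15 genes, 100 of 100 shifted 1.41-fold and 2 of 100 unshifted lists fell outside the central 95% of random lists. Unchanged genes in that run had a median error of 0.02 in log2. It therefore does not give the rate of detection among the real ratios, which also differ between genes for other reasons, such as length. For RNA and promoter accessibility together, only the computation of rho was checked. Over 8000 pairs of normally distributed values, not drawn from the libraries, a simulated rho of 0.48 was recovered as 0.50. This does not show how well a correlation would be recovered from counts. The runs on genes, peaks and lists model counting error and not differences between animals.

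Random lists matched on gene length as well used 10 expression and 5 length bins. Alternatives covered the scaling, the weight of each cell, the cell filter, doublets, thinning, clustering and the limits on low values. The motif analysis planned for accessible regions was not run, since no genome sequence was used here. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and bedtools 2.31.1.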

Results

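Single-cell RNA and chromatin accessibility were measured together in CD4+ T cells of donor origin, sorted from the mesenteric lymph nodes of mice 25 days after an allogeneic haematopoietic transplant. The assay, 10x Multiome, gives each nucleus an RNA profile and a profile of open chromatin (ATAC) under a shared barcode. The recipients were BALB/c mice, either wild type (WT) or lacking Ceacam1, a cell adhesion receptor found on epithelium and on activated T cells. They had first been turned into chimeras, animals with blood cells from another source, by irradiation and T cell-depleted bone marrow of WT BALB/c donors. The labels give the recipient genotype as IEC-Ceacam1-/-, after the intestinal epithelial cells, and the design names Ceacam1-/- mice given WT marrow, which leaves the gene missing outside the blood system. No value here checks where it was missing. After 2 months they were irradiated again and given splenocytes and T cell-depleted bone marrow of WT C57BL/6 donors, a mismatched graft whose T cells cause graft-versus-host disease (GVHD). The title of the series places the work in steroid-refractory GVHD of the gut, and the comparison asks how the donor T cells differ between the hosts.

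There was 1 library per host genotype and assay, so no value has a replicate and no difference was tested. Differences between the libraries may be those of single animals, pools, sorts or preparations. The WT host's matrix held 20000 barcodes with 162164382 RNA molecules (UMIs) and 338575416 ATAC counts. The Ceacam1-deficient host's held 20000 barcodes with 58417925 UMIs and 157450662 ATAC counts. After filtering, 15331 (76.7%) and 11094 (55.5%) barcodes were kept, with medians of 6368 and 1680 UMIs, 14093 and 5466 ATAC counts, and 4.58% and 6.38% mitochondrial UMIs. More than 10% mitochondrial UMIs were found in 2832 WT and 7123 Ceacam1-deficient barcodes. Below, values are given for the WT host first, CPM are counts of the summed cells scaled to the library's total, and ratios are log2 of the Ceacam1-deficient over the WT host. The 95% intervals in parentheses cover counting error only, except those of list medians, which are over resampled members.

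**Figure D1:**
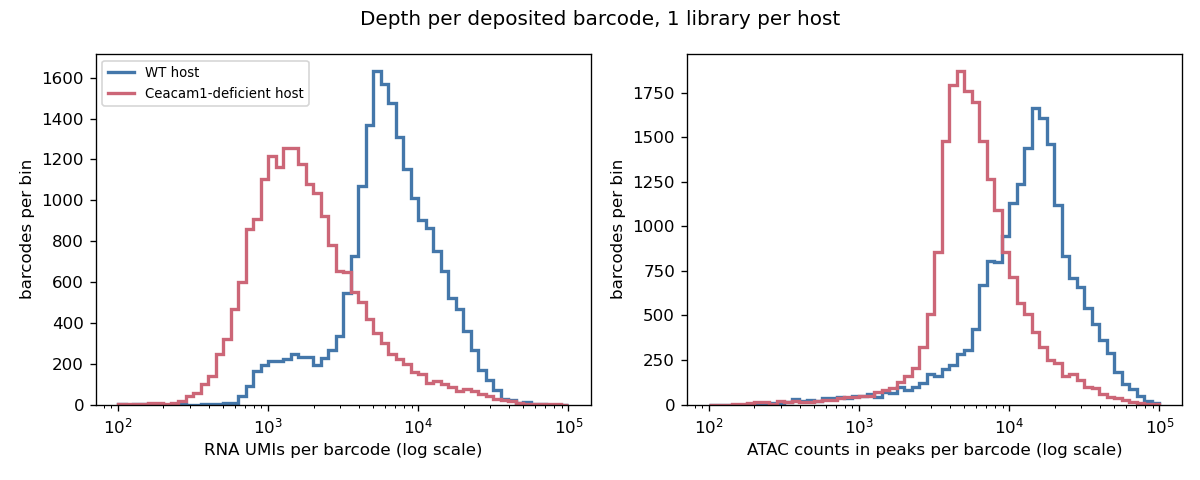
Barcodes per bin of RNA UMIs (left) and of ATAC counts in peaks (right) on log axes, for all deposited barcodes of the WT host and of the Ceacam1-deficient host. The median barcode held 6390 UMIs in the WT host and 1612 in the Ceacam1-deficient host.

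Ceacam1 itself (ENSMUSG00000074272; chromosome 7, 25461702 to 25477647, mm10) was almost undetected in both libraries. The WT host's cells gave 15 UMIs (0.125 CPM, 0.0698 to 0.206) and the Ceacam1-deficient host's 0, which allows up to 0.0987 CPM. These intervals overlap; that of the log2 ratio ended at -0.16, short of a ratio of 5 to 4, and no fold is given. The sorted cells come from WT donors, so their own Ceacam1 does not check the host label.

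Among single genes at 20 or more mean CPM that the fixed rule names, the lowest ratio was that of Jun (ENSMUSG00000052684; chromosome 4, 95049036 to 95052222), a subunit of the AP-1 transcription factor. It was 4.77-fold lower in the Ceacam1-deficient host, with a log2 ratio of -2.26 (-2.40 to -2.11; 51.9 and 10.9 CPM). Ifitm1, an interferon-induced membrane protein, had -2.09 (-2.17 to -2.02; 159 and 37.2 CPM), and Ly6c2, a surface marker of effector and memory T cells, -1.52 (-1.58 to -1.46; 179 and 62.4 CPM). The chemokine gene Ccl5 had -1.51 (-1.53 to -1.49; 1586 and 558 CPM), the interleukin-18 receptor gene Il18r1 -1.49 (-1.51 to -1.46; 1053 and 376 CPM), and the granzyme gene Gzma -1.40 (-1.44 to -1.37; 470.0 and 178 CPM). Ifng (ENSMUSG00000055170; chromosome 10, 118441046 to 118445894), the cytokine that defines type 1 responses, had -1.32 (-1.40 to -1.24; 96.9 and 38.8 CPM). The costimulatory ligand Cd86 (-1.55, -1.69 to -1.41), Txnip, a brake on glucose uptake (-1.34, -1.42 to -1.26), and the T cell kinase Txk (-1.31, -1.38 to -1.24) completed the 10 lowest.

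Il21 (ENSMUSG00000027718; chromosome 3, 37222759 to 37232636), a cytokine of follicular and other helper T cells, was 3.04-fold higher in the Ceacam1-deficient host, with a log2 ratio of 1.60 (1.49 to 1.71; 11.2 and 33.9 CPM). Also among the 10 highest were the orphan nuclear receptor Nr6a1 at 1.63 (1.55 to 1.72; 18.4 and 57.2 CPM), and the transcription factor Myb at 1.45 (1.39 to 1.52; 30.6 and 84.0 CPM). Kynu, an enzyme of tryptophan breakdown, had 1.59 (1.47 to 1.71; 10.0 and 30.2 CPM), and Tnfrsf8, which encodes CD30, had 1.27 (1.18 to 1.36; 18.8 and 45.4 CPM). The others were Nek1 (1.40, 1.31 to 1.48), Nav2 (1.36, 1.30 to 1.42), Taco1 (1.36, 1.31 to 1.40), Ccdc18 (1.31, 1.23 to 1.40) and Slc5a3 (1.27, 1.16 to 1.37). Nr6a1 and Myb are leading genes of cluster 6, Tnfrsf8 of cluster 9, Nav2 of cluster 10, Kynu and Nav2 of cluster 17, Il21 and Ifng of cluster 13, Ccl5 of cluster 1 and Ly6c2 of cluster 3, so the clusters described below are in part built on them. With clusters 0, 4, 6 and 14 left out, the ratios were 1.66 for Nr6a1, 1.53 for Myb, 1.52 for Tnfrsf8, 1.47 for Nav2, 1.70 for Kynu, 1.60 for Il21, -1.29 for Ifng, -1.63 for Ccl5 and -1.52 for Ly6c2.

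**Figure D2:**
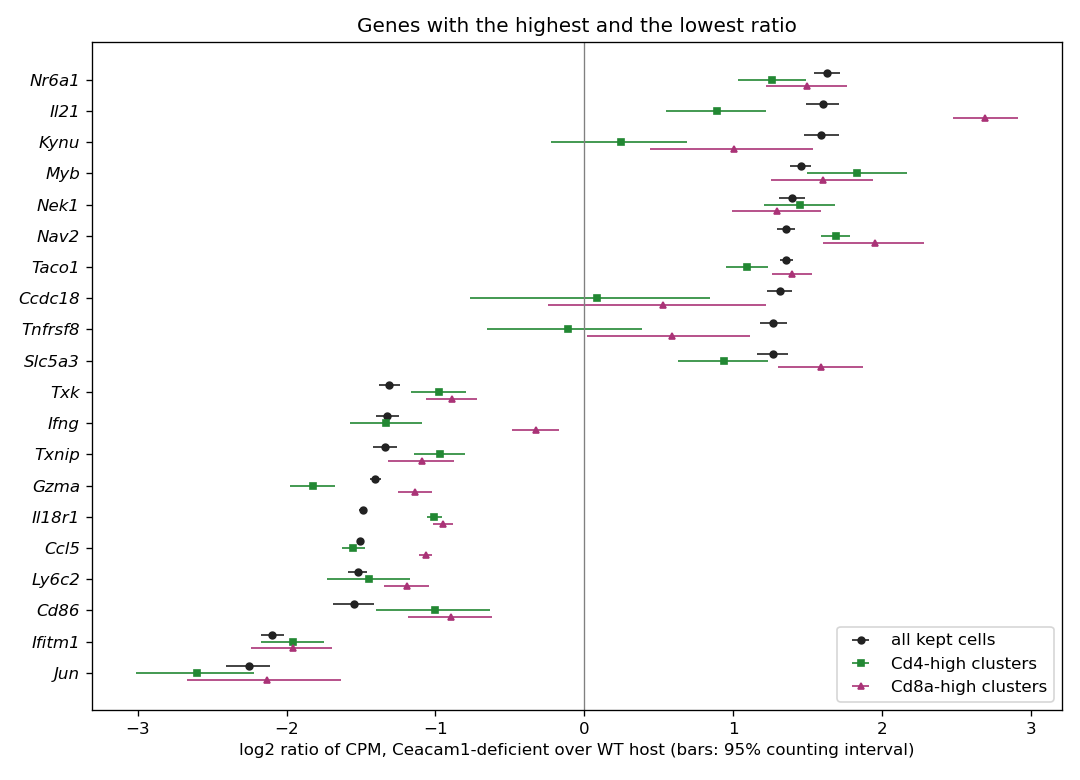
Log2 ratio of CPM (Ceacam1-deficient over WT host) of the 10 highest and 10 lowest named genes, in all kept cells (circles), Cd4-high clusters (squares) and Cd8a-high clusters (triangles), with 95% counting intervals. Ifng lies at -1.32 in all cells, -1.33 in the Cd4-high and -0.32 in the Cd8a-high clusters, and Il21 at 1.60, 0.89 and 2.70.

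Genes of cytotoxicity and of type 1 helper (Th1) cells were lower as groups in the Ceacam1-deficient host. The median ratio of the 15 cytotoxic genes at 5 CPM or more was -0.82 (-1.17 to -0.62), with 13 members lower and 1 higher, where a member counts as either from a ratio of 5 to 4 between the hosts. The natural killer receptors Klrd1 (-1.24, -1.35 to -1.14) and Klrk1 (-1.17, -1.28 to -1.06) stood beside Gzma and Ccl5, and the granzyme Gzmb had -0.62 (-0.65 to -0.59; 385 and 251 CPM). For the 16 Th1 genes the median was -0.68 (-1.29 to -0.28), with 11 lower and 0 higher. Tbx21, the master regulator of Th1 cells, did not share this direction, at 0.26 (0.22 to 0.31; 127 and 153 CPM), while Ccl5, Il18r1, Ifng and Txk had the lowest values of the list. Both medians lay at percentile 0 of 10000 random lists matched on mean expression, a description of these libraries and not a test. Markers of other cells moved as well. Cd8a (-0.85) and Cd8b1 (-1.11) were lower, as were, at low levels, Klrb1c (-1.85, -2.38 to -1.37), Klre1 (-1.73, -2.09 to -1.40) and Tyrobp (-2.14, -3.81 to -0.85) of NK cells and Tcrg-C1 (-1.77, -2.07 to -1.47) of gamma delta T cells, whereas Klra4 (1.10, 0.38 to 1.80) and Zbtb16 (0.83, 0.20 to 1.44) were higher.

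Cell cycle genes were higher as a group in the Ceacam1-deficient host. The median of the 25 cell cycle genes was 0.41 (0.16 to 0.66), at percentile 100, with 14 members higher, 1 lower and 10 between these limits. Within groups of clusters described below the median was 0.07 (Cd4-high), -0.10 (cell cycle-like) and 0.50 (Cd8a-high). The spindle and kinetochore genes Bub1 (0.98, 0.92 to 1.04), Aspm (0.96, 0.91 to 1.02), Tpx2 (0.87, 0.83 to 0.91) and Knl1 (0.77, 0.73 to 0.80) led the list, and Mki67, the proliferation marker, had 0.53 (0.50 to 0.55; 372 and 535 CPM). Among replication genes, picked after their values were seen and not tested against the others, Mcm2 had -0.15, Mcm6 0.18 and Pcna -0.33. The list's median was 1.58 among cells of 4000 to 8000 UMIs and 0.27 with no cell filter. Cell cycle-like cells had median depths of 11349 and 3589 UMIs, so that window takes in different classes of cells in the hosts.

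Immediate early and stress genes, interferon-response genes and glucocorticoid-response genes were also lower. In the immediate early list 13 of 16 genes were lower and 0 higher, with a median of -0.63 (-1.12 to -0.45; percentile 0). Beside Jun, the AP-1 genes Fosb (-1.89, -2.09 to -1.69) and Fos (-1.53, -1.74 to -1.34) and the heat-shock gene Hspa1b (-1.23, -1.33 to -1.14) had the lowest ratios. Among the 11 type I interferon genes 8 were lower and 0 higher (median -0.55, -0.90 to -0.19; percentile 0.01). They included Isg15 (-0.93, -1.13 to -0.74), Irf7 (-0.92, -1.10 to -0.73) and Zbp1 (-0.71, -0.80 to -0.63). Within the Cd4-high clusters described below this list had 0.05 (-0.43 to 0.16), with 2 higher and 4 lower. The glucocorticoid list, of interest to steroid resistance, had 9 lower and 2 higher of 15 (median -0.53, -0.94 to -0.04; percentile 0), but -0.21 over its 10 members at 20 CPM or more. Its lowest members were Txnip, Dusp1 (-0.97, -1.11 to -0.83), Pik3ip1 (-0.95, -1.12 to -0.79) and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at -0.94 (-1.05 to -0.83; 40.8 and 21.2 CPM). The receptor gene Nr3c1 itself had 0.16 (0.13 to 0.20; 248 and 278 CPM). Abcb1a, which encodes a drug efflux pump, had -1.04 (-1.11 to -0.97; 102 and 49.6 CPM), whereas the nuclear receptor and efflux list as a whole had a median of -0.11 (percentile 19.2) with 1 of 6 genes lower and 0 higher.

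The other helper lists differed less in all kept cells. The Th2 list had a median of 0.10 (percentile 67.3; 2 of 7 genes higher, 1 lower) and the Th17 and Th22 list -0.15 (percentile 6.84; 1 of 12 higher, 3 lower). The regulatory T cell (Treg) list had -0.01 (percentile 36.3; 4 of 15 higher, 4 lower) and the follicular helper (Tfh) list -0.11 (percentile 12.8; 3 of 10 higher, 1 lower). Medians within groups of clusters described below were often further from 0. The Th17 and Th22 list had -0.53 (-1.02 to 0.08) in the Cd4-high clusters (8 lower, 1 higher), of whose cells the Th17 and Th22-like cluster 2 held 2431 of 4876 and 190 of 751. It had -0.67 (-0.81 to -0.24) in naive and central memory-like cells and 0.36 (0.08 to 0.86) in the Cd8a-high clusters. In the Cd4-high and Cd8a-high clusters the Treg list had -0.28 (-0.55 to 0.10) and 0.25 (-0.10 to 0.61), the Tfh list 0.35 (0.09 to 0.73) and 0.28 (-0.05 to 0.86) and the Th2 list 0.11 (-0.46 to 0.20) and 0.37 (-0.09 to 0.60). Among their transcription factors were Gata3 at 0.01 (-0.05 to 0.06), Foxp3 at 0.41 (0.14 to 0.67) and Bcl6 at -0.57 (-0.71 to -0.44). Cytokine genes of the panel at low levels did not share a direction. Il22 had -1.60 (-1.84 to -1.36; 12.7 and 4.20 CPM), Il4 -1.46 (-1.90 to -1.05; 3.91 and 1.42 CPM), and Il2 -1.21 (-1.53 to -0.90; 5.93 and 2.57 CPM). Il17a had -0.99 (-1.31 to -0.68; 5.20 and 2.62 CPM) and Il10 -0.75 (-0.96 to -0.55; 10.8 and 6.45 CPM). Il13 was higher at 0.97 (0.59 to 1.34; 1.36 and 2.65 CPM) but had -0.21 among cells of 4000 to 8000 UMIs, while Csf2 had -0.12 (-0.48 to 0.22) and Tnf -0.28 (-0.42 to -0.14). In the Tfh list Cd200 (0.72, 0.59 to 0.86) and Tox2 (0.42, 0.35 to 0.49) were higher with Il21, and in the Treg list Ikzf2 (0.63, 0.59 to 0.66) was higher and Capg (-0.60, -0.69 to -0.51) lower.

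Of the gut homing genes in the panel, Ccr9, the receptor that draws T cells to the small intestine, was higher at 0.54 (0.48 to 0.60; 66.5 and 96.6 CPM). The integrin subunits Itga4 (0.10, 0.09 to 0.12) and Itgb7 (-0.23, -0.27 to -0.20) were close to equal. The homing and tissue residence list had a median of -0.35 (-0.58 to -0.20; percentile 0.01), with 9 of 16 genes lower and 2 higher. It had -0.26 (-0.48 to 0.13) in the Cd4-high and -0.10 (-0.30 to 0.23) in the Cd8a-high clusters, where both intervals included 0. Ccr2 (-0.99, -1.05 to -0.94), Itga1 (-0.84, -0.90 to -0.79) and Cxcr6 (-0.80, -0.84 to -0.76), receptors of inflamed or resident T cells, were among the lowest, and Cxcr3 had -0.33 (-0.39 to -0.27).

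Naive and central memory genes had a median of -0.37 (percentile 0.17; 7 of 11 lower, 0 higher). The direction did not hold in the Cd4-high clusters, where the median was 0.19 (4 higher, 1 lower), and it was 0.08 in Th2-like and -0.05 in naive and central memory-like cells. The repressor Bach2 (-0.68, -0.74 to -0.62) and Il7r (-0.53, -0.55 to -0.50) were the lowest, and Tcf7 had -0.18 (-0.24 to -0.11). Ccr7, a lymph node homing receptor under 5 CPM and so outside the median, had 0.10 (-0.17 to 0.36). The coinhibitory and exhaustion list had -0.12 (percentile 6.43; 4 of 14 lower, 1 higher), and its receptors Pdcd1 (-0.12, -0.20 to -0.05) and Havcr2 (-0.02, -0.08 to 0.04) were close to equal. Activation and costimulation genes had -0.04 (percentile 22.6; 3 of 16 lower, 2 higher), with Cd69 at -0.65 (-0.71 to -0.59). Cytokine receptors had -0.19 (percentile 0.83; 5 of 18 lower, 2 higher), and -0.02 and -0.07 in the Cd4-high and Cd8a-high clusters. Survival and apoptosis genes had -0.28 (percentile 0.16; 7 of 15 lower, 1 higher), with the pro-apoptotic Bbc3 (-0.98, -1.21 to -0.76), Bcl2l11 (-0.62, -0.69 to -0.55) and Bax (-0.54, -0.61 to -0.47) all lower. That list's median was -0.02 among cells of 4000 to 8000 UMIs, and -0.02 and -0.01 in the Cd4-high and Cd8a-high clusters. Over all kept cells, not within groups of clusters, the metabolic lists stood near 0, with a median of 0.05 for 16 glycolysis genes (percentile 53.9, 1 higher, 0 lower). The median was -0.01 for 14 genes of fatty acid and oxidative metabolism (percentile 36.1; 0 higher, 0 lower), and the hexokinase gene Hk2 had 0.52 (0.44 to 0.60).

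**Figure D3:**
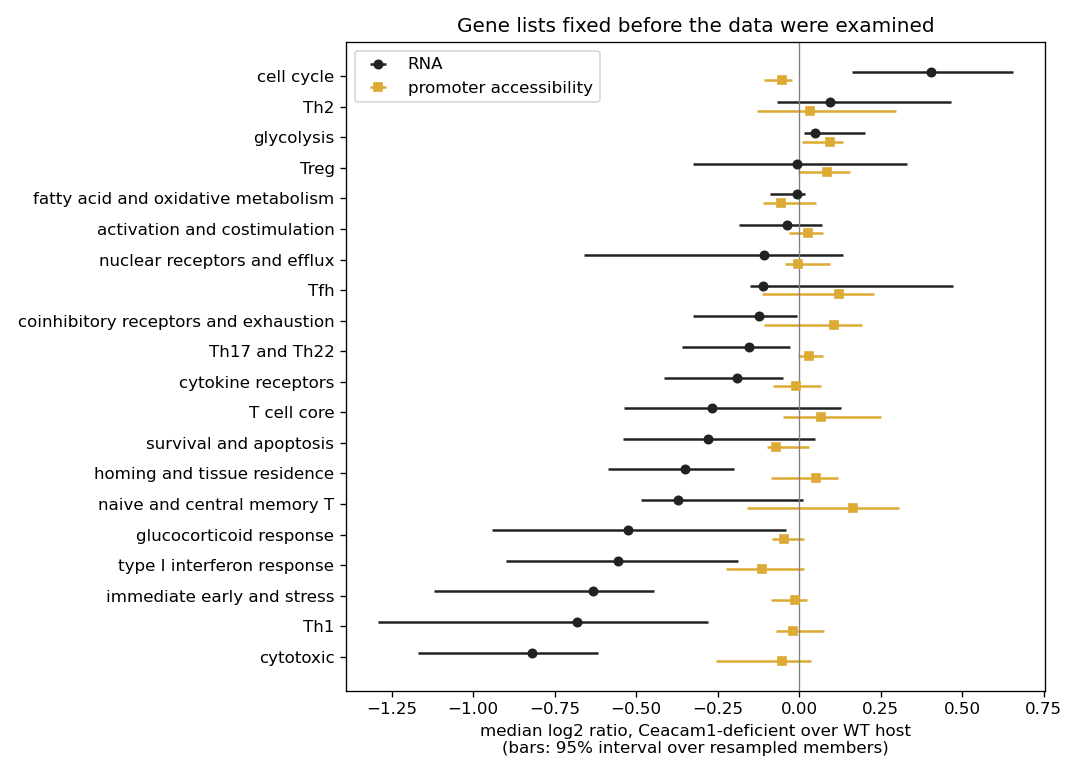
Median log2 ratio (Ceacam1-deficient over WT host) of each of the 20 gene lists for RNA (circles) and for promoter accessibility (squares), with 95% intervals over resampled members. RNA medians run from -0.82 for cytotoxic genes to 0.41 for cell cycle genes, while promoter medians run from -0.11 to 0.17. Promoter medians are over members at 20 or more promoter CPM, so the members differ from those for RNA.

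Ratios followed gene length, from a median of -0.19 in the shortest of 5 equal groups of genes to 0.17 in the longest. Over random lists matched on length as well, the cytotoxic and Th1 lists stayed at percentile 0 and the cell cycle list at 100.

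Both libraries held cells with RNA of either T cell coreceptor, although the cells were sorted on CD4. Cd4 had 0.06 (0.01 to 0.11; 116 and 120.4 CPM), while Cd8a, a gene of CD8 T cells, had -0.85 (-0.89 to -0.81; 275 and 152 CPM) and Cd8b1 -1.11 (-1.15 to -1.06; 272 and 126 CPM), a median over this marker pair of 273 and 139 CPM. The T cell core list had a median of -0.27 (6 of 14 genes lower, 0 higher; percentile 0.52), and -0.06 and -0.07 in the Cd4-high and Cd8a-high clusters, with Trbc2 at -0.87 (-0.90 to -0.85) and Cd3e at -0.30 (-0.34 to -0.27) in all kept cells. By list medians, which can hide single members, markers of other cells were scarce. The B and plasma cell lists leave out Igkc, which had 1077 CPM in cluster 4, described below. Median CPM per list were 0.357 and 0.455 for B cells and 1.34 and 0.241 for plasma cells. They were 0.233 and 0.214 for macrophages and monocytes and 2.59 and 0.990 for dendritic cells. Neutrophils and mast cells had 0.166 and 0.147. Innate lymphocyte lists had 1.60 and 0.896 (NK and ILC) and 7.33 and 2.73 (gamma delta and innate-like T). Stroma, endothelium and epithelium had 0.129 and 0.0669, erythroid cells and megakaryocytes 0.0416 and 0, and immature thymocyte-like cells 0.154 and 0.455. The most abundant members of some lists are genes that T cells express too, among them Themis (thymocytes), Id2 (NK and ILC), Pecam1 (endothelium), Prdm1 (plasma) and Ly6c2 (monocytes). Among sex-linked genes Xist had 0.0998 and 0.294 CPM, Tsix 0.258 and 1.77, and the Y-linked Ddx3y 138 and 123.

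Clustering of the RNA profiles placed the cells of the hosts largely in different clusters. Clusters 0, 4 and 6, which carry no name, held 3.40% (3.12 to 3.70) of the WT host's cells and 68.6% (67.7 to 69.5) of the Ceacam1-deficient host's. Cluster 0 was led by Gm42418 and AY036118, which overlap ribosomal RNA, cluster 4 by immunoglobulin genes such as Igkc at 1077 CPM together with S100a8 and S100a9, and cluster 6 by Supt3, Nr6a1 and Myb. Leading genes were taken over the cells of both hosts together. Jchain, another leading gene of cluster 4 (63.9 CPM), had 290 UMIs in all kept WT cells and 6 in the other host's. Its level in that cluster thus came mostly from the WT host's 388 cells there, not from the other's 1806. The other leading genes were not split by host. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Their median depths were 4679 and 1229 UMIs in cluster 0, 2078 and 1004 in cluster 4 and 10914 and 2314 in cluster 6.

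Every named T cell class took a smaller share of the Ceacam1-deficient library. Th17 and Th22-like cells (led by Il1r1, Il17re and Il23r) were 15.9% (15.3 to 16.4) of the WT host's cells and 1.71% (1.48 to 1.97) of the Ceacam1-deficient host's. Th2-like cells (Il1rl1 among the leading genes) were 10.7% (10.2 to 11.2) of the WT host's cells and 2.22% (1.95 to 2.51) of the Ceacam1-deficient host's, but 4.11% and 0.778% without a mitochondrial limit and 6.78% and 1.05% with depths matched rank by rank. Cell cycle-like cells were 21.4% (20.8 to 22.1) of the WT host's cells and 13.6% (12.99 to 14.3) of the Ceacam1-deficient host's. Naive and central memory-like cells made up 5.25% and 2.84%, Treg-like cells 0.698% and 0.270%, interferon-like cells 0.417% and 0.0811%, and the unnamed cluster 9, led by Tnfrsf8, 3.89% and 4.81%. These shares were taken from joint clusters at unequal depth, after a CD4 sort and a filter that removed more cells of the Ceacam1-deficient host. The named clusters are led by members of the lists they are named from, such as Foxp3 and Ikzf2 (Treg-like), Tcf7 (naive and central memory-like) and Aspm (cell cycle-like), so these shares and the ratios of those genes are not independent. Clusters 0, 4, 6 and 14, set aside after the data were seen, held 5.29% and 69.5%. Without them cell cycle-like cells were 22.6% and 44.7%, naive and central memory-like 5.54% and 9.31%, and Treg-like 0.737% and 0.887%. Th17 and Th22-like cells were then 16.7% and 5.62% and Th2-like cells 11.3% and 7.27%.

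**Figure D4:**
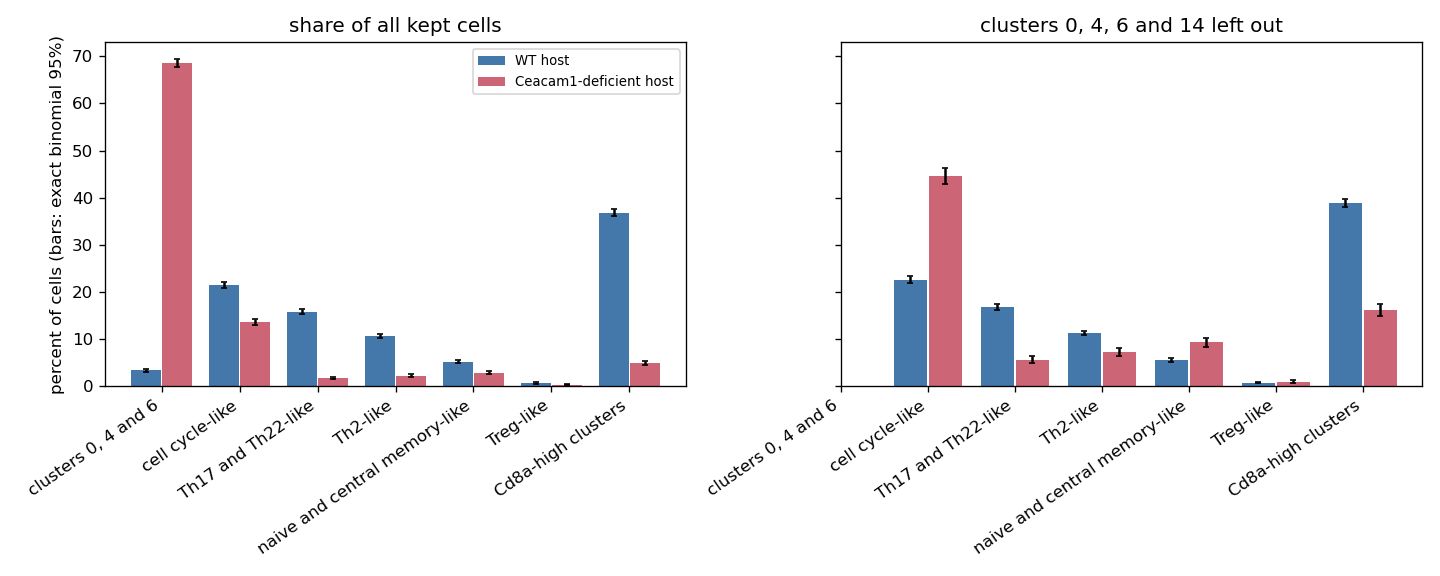
Percent of cells per class in the WT and the Ceacam1-deficient host, of all kept cells (left) and with clusters 0, 4, 6 and 14 left out (right), with exact binomial 95% intervals. Cell cycle-like cells are 21.4% and 13.6% on the left and 22.6% and 44.7% on the right.

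Type 1 and cytotoxic genes were lower in the Ceacam1-deficient host within the Cd4-high clusters and were nearer to equal within the Cd8a-high clusters. Over both lists together the median was -0.82 (-0.996 to -0.35) in the former and -0.22 (-0.39 to -0.09) in the latter. Members of these lists are among the 10 leading genes of clusters 1 (Ccl5), 12 (Ccl3) and 13 (Ifng, Ccl3 and Ccl4), all Cd8a-high. They are not among those of the Cd4-high clusters. Clustering on such genes may itself bring the hosts nearer to equal in the Cd8a-high clusters, so the contrast between the groups is not independent of it. In the Cd4-high clusters 2, 7 and 10 (4876 and 751 cells) the median was -0.90 for cytotoxic genes (-1.60 to -0.51), -0.49 for Th1 genes (-0.98 to -0.04) and -0.72 for immediate early genes. The cell cycle list there had 0.07, the Tfh list 0.35, Ifng -1.33, Gzmb -1.06 and Il21 0.89. The group includes the Th2-like cluster 7, whose cells serve as background for Ifng in the shares below. Whether the Ifng ratio in this group is one of background RNA was not tested, and no order is read from it. The CD8 T cell genes Cd8a and Cd8b1 were lower there too, at -0.81 (-1.06 to -0.56) and -1.14 (-1.38 to -0.91). In the Cd8a-high clusters 1, 3, 12, 13 and 16 (5652 and 545 cells) the cytotoxic median was -0.25 (-0.46 to 0.27), the Th1 median -0.19 (-0.58 to 0.05), the cell cycle median 0.50, Ifng -0.32 and Il21 2.70. The groups differ in make-up: clusters 2, 7 and 10 held 2431, 1640 and 805 WT and 190, 246 and 315 Ceacam1-deficient cells. Cluster 13, led by Ifng and Il21, held 405 and 103 of the Cd8a-high cells and had Cd4 at 132 CPM. With each cell thinned to 1000 UMIs, Cd8a or Cd8b1 without Cd4 was found in 53.7% and 36.6% of the Cd8a-high cells. Cd4 without either was found in 3.24% and 7.88%. Ratios in this group, such as those of Il21 and Ifng, can therefore follow its make-up. Cell cycle-like cells (3287 and 1511), most of which lay in clusters 5 and 8 in the WT host and in clusters 5 and 11 in the other, had -0.73 for cytotoxic and -0.10 for cell cycle genes. The cytotoxic median was -1.20 in Th2-like cells and -0.70 in naive and central memory-like cells. Both groups of clusters were put together from their Cd4 and Cd8a levels after the data were seen and take 31.8% and 6.77% (Cd4-high) and 36.9% and 4.91% (Cd8a-high) of the cells.

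Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs, which left out 165 WT and 2300 Ceacam1-deficient cells. Mki67 was found in 18.6% and 34.8% of cells (47.7% and 52.5% unthinned), against 5.24% and 7.98% in Th2-like cells, which lie outside the cycling clusters and had median depths of 5176 and 4882 UMIs. Il21 was found in 0.831% and 2.60% (4.25% and 5.88% unthinned), against 0.417% and 0.588% in cluster 3, a Cd8a-high cluster with median depths of 6006 and 5950. Ifng was found in 7.86% and 3.79% (32.9% and 8.69% unthinned), against 7.07% and 1.26% in Th2-like cells; the WT share lay close to this background, and no order is read from it. Cd4 was found in 11.1% and 10.7% of cells (40.1% and 22.2% unthinned), against 2.55% and 2.94% in cluster 3, which has little Cd4. No background share is given here for Tbx21 (11.3% and 13.99%), Prdm1 (7.35% and 8.49%), Ccr9 (5.30% and 8.24%), Itga4 (64.7% and 69.9%) and Nr3c1 (20.1% and 22.1%). The order of these thinned shares was opposite to that of the unthinned shares (46.4% and 27.9%, 33.3% and 18.4%, 21.9% and 16.8%, 92.8% and 81.7% and 61.6% and 38.4%), and no order is read from them.

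The peak lists of the hosts largely overlapped, and ratios at the shared regions with the most counts centred near 0. The libraries' peak lists held 108406 and 108833 peaks, of which 87.2% (87.0 to 87.4) and 86.9% (86.7 to 87.1) overlapped a peak of the other list, and promoter peaks were 15.6% and 15.4%. The 94479 regions with a peak in both held 98.6% and 98.6% of the ATAC counts. Among the 13647 at 20 or more ATAC CPM the median ratio was -0.03, with quartiles of -0.12 and 0.06.

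By the CPM of whole regions, the highest ratios were at distal regions (mm10): chromosome 2, 17869962 to 17870857, 126101 bp from H2al2a, at 1.76 (1.66 to 1.85), and chromosome 7, 30448428 to 30449363, in Kirrel2 and near Aplp1, at 1.73 (1.65 to 1.80). Next was chromosome 15, 99684507 to 99685437, near Asic1, at 1.65 (1.54 to 1.76). They were followed by chromosome 17, 88273872 to 88274767, in Gm31615, at 0.99 (0.88 to 1.10) and chromosome 6, 146221558 to 146222267, in the body of Itpr2, at 0.84 (0.75 to 0.93). The promoter of Gabbr1 (chromosome 17, 37046526 to 37047203) stood at -0.82 (-0.94 to -0.70), where the peak covered 678 bp in the WT host and 425 bp in the other. A distal region in Irak2, a kinase of interleukin-1 and Toll-like receptor signalling (chromosome 6, 113654656 to 113655561), had -0.76 (-0.88 to -0.64). Distal regions near Heca (chromosome 10, 17946764 to 17947496), Osbpl1a (chromosome 18, 12948831 to 12949747) and Gm7160 (chromosome 1, 105980623 to 105981613) had -0.69 (-0.81 to -0.56), -0.68 (-0.81 to -0.56) and -0.66 (-0.78 to -0.54). Per covered kb the ratios of the 5 high regions, in the order above, were 1.76, 1.66, 1.60, 0.97 and 0.41, and those of the low ones -0.14, -0.76, -0.59, -0.69 and -0.80. The peak at Itpr2 covered 492 bp in the WT host and 661 bp in the other. Without clusters 0, 4, 6 and 14 the high regions had 1.14, 1.12, 1.21, 0.62 and 0.81 and the low ones -0.76, -0.70, -0.62, -0.64 and -0.54. Within the Cd4-high clusters the values were 0.91, 0.89, 1.08, 0.37 and 0.70 and -0.52, -0.46, -0.59, -0.64 and -0.62, and within the Cd8a-high clusters 1.05, 1.04, 1.16, 1.05 and 0.66 and -1.19, -0.54, -0.72, -0.43 and 0.04. In the latter the interval of the region near Gm7160 included 0 (-0.27 to 0.34).

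Promoter medians of the 20 lists spanned a narrower range than RNA medians, but not over the same members. They took members at 20 or more promoter CPM whatever their RNA level, such as 9 cytotoxic and 4 Th17 and Th22 genes. Median promoter ratios were -0.02 for Th1 (percentile 87.6), -0.05 for cytotoxic (percentile 66.4; -0.35 within the Cd4-high clusters, -0.56 to 0.06), -0.05 for cell cycle (percentile 55.4) and -0.01 for immediate early genes. The type I interferon list had the lowest, -0.11 (percentile 25.8). The median was 0.17 for 8 naive and central memory genes (-0.16 to 0.31; percentile 100). Also at high percentiles were glycolysis (100), coinhibitory (99.9), Treg (99.8), Tfh (99.6), T cell core (99.5), activation (98.5) and homing (97.7) genes. Their medians were small, from 0.03 (activation) to 0.12 (Tfh). The interval over members spanned both signs for all of them but glycolysis (0.008 to 0.14). Within the Cd4-high clusters the median was -0.09 for Treg and -0.03 for activation genes, and positive for the others. The promoters of Ifng (-0.39, -0.48 to -0.31), Il21 (0.40, 0.28 to 0.51), Myb (0.34, 0.25 to 0.44) and Nav2 (0.36, 0.28 to 0.44) went in the direction of their RNA. So did those of Abcb1a (-0.29, -0.40 to -0.18), Txnip (-0.28, -0.36 to -0.21) and Ccr9 (0.29, 0.16 to 0.41). Promoters of Jun (-0.09, -0.13 to -0.04), Ccl5 (-0.05, -0.16 to 0.05), Gzma (0.04, -0.08 to 0.15), Il18r1 (-0.02, -0.11 to 0.07), Nr6a1 (0.00, -0.06 to 0.06) and Cd8a (0.01, -0.10 to 0.12) were close to equal. Across 8443 genes Spearman's rho between the RNA and promoter ratios was 0.09 (0.07 to 0.11 over resampled genes). Genes are not independent replicates, and no p is given.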

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

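Values over cells of 4000 to 8000 UMIs, without clusters 0, 4, 6 and 14, without a mitochondrial limit and with depth matched rank by rank were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each genotype has 1 library and no result comes from a test. No list among those outside the central 95% of random lists changed sign over 12 alternatives. Of the 240 values of all 20 lists, 163 lay within a counting interval of the median and 77 outside it. That interval came from 1000 Poisson draws of the counts and is not the printed interval over members. Of 1150 values of named genes 786 stayed within the gene's counting interval and 363 moved. The other 1, of a gene whose interval had excluded a ratio of 5 to 4, changed sign: Il13 at -0.21 among cells of 4000 to 8000 UMIs. The Th1 median (-0.68) was -0.80 with every cell weighted alike, -0.63 without clusters 0, 4, 6 and 14 and -0.75 for members at 20 CPM. The cytotoxic median (-0.82) was -0.97 with every cell weighted alike, -0.74 under the strict filter and -0.75 without those clusters. The cell cycle median (0.41) was 0.77 with every cell weighted alike, 0.27 with no filter, 0.80 under the strict filter, 0.32 with doublets, 0.32 without a mitochondrial limit, 1.58 among cells of 4000 to 8000 UMIs and 0.50 without those clusters. In each other clustering, a cluster took the main class most frequent among its cells, so these shares are not independent of the main clusters. With each library clustered alone, the class was taken within that library, so that value is no separate check. The share of clusters 0, 4 and 6, or of clusters given their class, was higher in the Ceacam1-deficient host by 65.2 points. The gap was 73.1 without thinning, 70.4 at resolution 0.5, 59.6 at resolution 2 and 57.2 under the strict filter. It was 64.0 with doublets, 62.5 with depth matched, 57.7 without a mitochondrial limit and 64.1 with each library clustered alone. The cell cycle-like share (-7.82 points) was -15.0 (no thinning), -11.0 (resolution 0.5), -5.54 (resolution 2), -10.8 (doublets kept), -6.61 (alone) and -5.18 (no mitochondrial limit), and changed sign to 0.839 under the strict filter and 22.04 with clusters 0, 4, 6 and 14 out of the total. The Th2-like share (-8.48 points) ran from -12.0 without thinning to -3.34 without a mitochondrial limit, by way of -5.73 with depth matched. The naive and central memory-like share changed sign under the same pair of alternatives as the cell cycle-like share, to 0.438 and 3.77, and the Treg-like share with those clusters out, to 0.150; leaving clusters out shrinks the total. Without thinning, shares of cells with a UMI changed sign for Tbx21 (-18.5 points), Prdm1 (-14.9), Ccr9 (-5.09), Itga4 (-11.1) and Nr3c1 (-23.1), where the libraries' depths differ. For peaks at 5 CPM the overlap was 93.6% and 92.7%. Promoter medians were 0.0230 (strict) and 0.0151 (without those clusters) for Th1, -0.00790 (no filter) and -0.16 (without those clusters) for cytotoxic genes, and -0.000797 with no filter for activation and costimulation genes, a change of sign from 0.03. The rank correlation of RNA and promoter ratios was 0.13 for genes at 1 CPM and 5 promoter CPM. Except where the construction shows it, the cause was not tested. A restriction to clusters with Cd3e removes no cell, as all 18 clusters carry it (169 to 493 CPM). This does not show that every kept barcode is a T cell, since mixed or free RNA would carry Cd3e too. Cluster 4, led by immunoglobulin genes, had Cd3e at 271 CPM. Motif content, over the centre or the whole region, was not run without a genome.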

Other observations

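Some genes differed between hosts in the Cd4-high clusters in another way than in the Cd8a-high clusters, groups and genes chosen after the data were seen; these differences were not tested. Clusters 2, 7 and 10, pooled as Cd4-high, held 2431, 1640 and 805 WT cells and 190, 246 and 315 Ceacam1-deficient cells, so a pooled ratio can follow this make-up. The make-up of the Cd8a-high group differed between the hosts too, as given above. Il10 had -3.19 (-5.48 to -1.63) in the Cd4-high clusters (213 and 3 UMIs), -4.16 (-9.47 to -1.65) in the Th2-like cluster 7 alone (124 and 1 UMIs) and 0.18 (-0.22 to 0.55) in the Cd8a-high clusters. In the Cd4-high and Cd8a-high clusters, Ahr, a receptor for dietary and microbial ligands, had -0.85 (-1.09 to -0.62) and 1.07 (0.81 to 1.31), and Tnfrsf9, an activation receptor, -1.17 (-1.69 to -0.69) and 0.57 (0.37 to 0.76). Ikzf2 was higher in both groups, at 1.06 (0.95 to 1.16) and 0.73 (0.62 to 0.84), as was Myb, at 1.84 (1.496 to 2.17) and 1.60 (1.252 to 1.94).

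Pparg, a lipid-sensing nuclear receptor of Th2 cells and Tregs, was higher in the Ceacam1-deficient host in RNA (0.74, 0.58 to 0.90) and at its promoter (0.79, 0.58 to 1.00). Rtp4, an interferon-induced gene, was lower in both, at -0.90 (-1.10 to -0.70; 11.7 and 6.26 CPM) in RNA and -0.45 (-0.66 to -0.25) at the promoter. Il17a and Il22 went apart, with RNA ratios of -0.99 (-1.31 to -0.68) and -1.60 (-1.84 to -1.36) but promoter ratios of 0.71 (0.36 to 1.05) and 0.51 (0.16 to 0.85). Promoters of the integrin genes Itga4 (0.33, 0.28 to 0.39) and Itgb7 (0.25, 0.13 to 0.37) were more open, with RNA ratios of 0.10 (0.09 to 0.12) and -0.23 (-0.27 to -0.20).

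Of the tests that follow, those over cells of 4000 to 8000 UMIs, of Cd8a and Cd8b1 in the Cd4-high clusters and of the share of cycling cells were chosen after the result had been seen, and the co-detection test was read at 1000 UMIs after its values at 500, 1000 and 2000 UMIs were known. The 29 Th1 and cytotoxic genes together had a median ratio of -0.75 (-1.05 to -0.46). Fewer Cd8a-high cells in the Ceacam1-deficient library stay open: the median within the Cd4-high clusters was -0.82 (-0.996 to -0.35), beyond the limit of -0.2 set against them, but that limit took no account of RNA from other cells, and Cd8a (-0.81, -1.06 to -0.56) and Cd8b1 (-1.14, -1.38 to -0.91) were lower by about as much in these barcodes. A trend with gene length is argued against by a percentile of 0 among random lists matched on expression and length, and barcodes of few UMIs by a median of -0.64 (-1.08 to -0.33) among cells of 4000 to 8000 UMIs, a window that differs in its classes of cells between the hosts. The host's genotype and anything else that differs between the libraries, such as handling or the state of the animals, were not tested and stay open.

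Cell cycle genes were higher in the Ceacam1-deficient host over all kept cells, though not within the cell cycle-like cells. A trend with gene length is argued against by a percentile of 100 among lists matched on expression and length. Whether more of its cells were cycling cannot be told apart from what the unnamed clusters are. With depths matched rank by rank the cell cycle-like share differed by -7.25 points (20.7% and 13.5%), which goes against a larger share, but by 22.04 points with clusters 0, 4, 6 and 14 out of the total. The share of all kept cells with a Mki67 UMI, given above, was higher in that host both thinned and unthinned, which goes with a larger share for this marker alone. The host's genotype stays open and was not tested.

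Clusters 0, 4 and 6 held most cells of the Ceacam1-deficient host. Lower depth alone is argued against by the run with depths matched rank by rank. There the clusters in which their cells were most frequent held 4.91% of the WT cells and 67.4% of the others. That WT share is 7.28% of the other. Mixed or free RNA stays open: Cd4 and Cd8a or Cd8b1 were found together 0.752 (0.606 to 0.921) times as often as chance gives, in an interval that spans the limit of 0.8 set for it, and 0.883 (0.637 to 1.19) and 0.766 (0.636 to 0.914) at 500 and 2000 UMIs. At 1000 UMIs that host's Cd4-high clusters gave 0.716 (0.328 to 1.35), its Cd8a-high clusters 0.377 (0.152 to 0.771) and its clusters other than 0, 4, 6 and 14 together 0.415 (0.296 to 0.566), and the WT cells of clusters 0, 4 and 6 gave 0.406 (0.164 to 0.831); a pool of Cd4-high and Cd8a-high cells lowers the value, so the comparison does not decide. Neither cells in a poor state nor a cell state brought about by the host's genotype was tested. Median mitochondrial shares in that host were 6.75%, 7.07% and 6.00% in clusters 0, 4 and 6. The median was 6.38% over its kept cells, most of which lie in these clusters. Its other clusters ran from 3.89% (Th2-like) to 6.70% (cluster 11). Among them were 4.54% in Th17 and Th22-like and 4.62% in naive and central memory-like cells, but 6.22% in cluster 5 and 6.51% in cluster 9.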
